A study of Homo sapiens with 6 samples.

How the data were processed

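The series holds 6 arrays of an established human multiple myeloma cell line, 3 from cells given 0 Gy and 3 from cells given 6 Gy of carbon ions, with RNA extracted 1 day after irradiation. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin by the manufacturer's procedure. The labels number the samples 1 to 3 within each dose and do not say whether these are separate cultures, so p-values measure the spread between these samples, which may be technical.

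The file used is the deposited table of 33297 probe set values per array, and the authors' values were read as log2 intensities. The base of the logarithm is inferred from the range of the values, about 2 to 14 on every array, and every fold printed here rests on it. The normalization method, the software and the background correction are not given in the sources used here. The arrays have nearly equal medians and quartiles, as scaling to one another would give, but whether they were scaled is not given either. The upper quartile was slightly lower on the irradiated arrays (7.87 to 7.91) than on the unirradiated arrays (7.92 to 7.96). Array medians were 5.67, 5.67 and 5.64 for unirradiated replicates 1 to 3 and 5.66, 5.69 and 5.72 for irradiated replicates 1 to 3. Such scaling would remove a shift common to all transcripts, so differences are read as relative to the bulk of the transcripts. The median log2 difference over all 18417 genes was 0.04 rather than 0, and list medians are to be read against it. The table gives no detection calls, so whether a dim gene lies above background is unknown; the lower quartile of the values lay between 3.89 and 3.97. Scanner files were not used here.

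Probe sets were named from the platform annotation given for this array design, which can be old and listed 1 gene symbol for 19460 probe sets, several for 1754 and none for 12083. Of the 19460, 19429 matched a current RefSeq gene through the Entrez ID, and 0 symbols had to be updated. Where several probe sets named a gene (769 genes), the one with the highest mean over all 6 arrays was used, which gave 18417 genes. Probe sets with several genes or no listed gene were left out of the gene tests. No genome build is named with the values, so no coordinates are given. RefSeq gene names, transcript types and gene lengths were taken from the annotation of GRCh38.p14.

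Irradiated and unirradiated arrays were compared on the deposited log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with no covariate and no filter on dim genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed, and "rose" and "fell" are used of these alone. The moderated test had 4 residual and 5.85 prior degrees of freedom. An exact permutation test of a single gene with 3 arrays against 3 cannot give a two-sided p under 0.1, so none was run per gene. Standard errors are those of limma and standard deviations are over the 3 arrays of a group. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

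The test, the threshold, the alternatives, 31 gene lists and the rule for naming genes were chosen before the data were examined. The rule named the 12 largest increases and 12 largest decreases among changed genes whose groups do not overlap, the 3 members with the smallest p of each list with at least 3 measured members, and CDKN1A, MDM2, CCNB1, MKI67, PCNA, MYC, MCL1, IRF4, ACTB and GAPDH; a further gene of the rule is not reported here. Mitochondrially encoded genes had 0 measured members, which left 30 lists. Lists were tested with camera of limma at a preset correlation of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry were run beside it; fry asks whether a list's genes move one way on balance and does not compare them with other genes. Counts of members are given over all genes tested and adjusted over the list alone.

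The limma steps were tested on simulated data of 18417 genes with the real means and spreads and 50 changed genes at each of 4 sizes. They recovered 16% of changes of 0.25 on the log2 scale, 98% of changes of 0.5 and 100% of changes of 1 and of 2, with 7 false calls. The p cutoff under Benjamini-Hochberg is looser where more genes pass, and 2676 genes passed in the data. The simulated shares, above all that for small changes, thus need not hold for the data. Camera recovered a simulated shift of the ATF4 list and called 0 of the 29 other lists; the simulated genes varied independently, which real genes need not.

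Alternatives tried were the sample number as a replicate block, each array left out in turn, no genes from the dimmest 33.3%, quantile normalization, subtraction of array medians, an intensity trend with a robust prior, array weights, the mean of all probe sets of a gene, all probe sets, an adjusted p under 0.01, fold minimums of 1.5 and 2, a plain equal-variance test, camera with an estimated correlation and fry. For some list medians, 95% intervals come from 2000 bootstrap resamples of the list's genes, which are not independent of each other.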

Results

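The cells were an established human multiple myeloma line, grown from malignant plasma cells. They received 0 or 6 Gy of carbon ions, a form of particle radiation that deposits its energy densely along its track, and total RNA was taken 1 day later. Gene expression was measured on 6 biotin-labelled, 1-colour arrays, 3 from unirradiated and 3 from irradiated cells. The comparison asks which transcripts differ between irradiated and unirradiated myeloma cells at that time. The median deposited log2 value lay between 5.64 and 5.67 on the unirradiated arrays and between 5.66 and 5.72 on the irradiated arrays. The number of arrays limits the precision, and the median standard error (SE) of a gene's log2 difference was 0.08.

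Irradiated cells held far less mRNA of replication-dependent histones and of genes driven by the stress transcription factor ATF4, and more mRNA of several HLA class II, chemokine and heat shock genes. The largest decrease was that of CHAC1, an ATF4 target whose enzyme degrades glutathione, from a log2 value of 9.56 ± 0.22 to 6.51 ± 0.27 (mean ± SD, n = 3), which is 8.28-fold lower. The linker histone gene H1-3 was 5.61-fold lower, with a log2 difference of -2.49 ± 0.13 (SE). The largest increase was that of IL32, which encodes a pro-inflammatory cytokine, from 6.97 ± 0.14 to 8.85 ± 0.07 (mean ± SD, n = 3), or 3.70-fold. CXCL9, encoding a chemokine that attracts activated T cells, was 3.36-fold higher, with a log2 difference of 1.75 ± 0.15 (SE). The limma adjusted p was 6.29e-06 for CHAC1 and for IL32, 9.15e-06 for H1-3 and 9.22e-05 for CXCL9.

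Of 18417 genes tested with limma, 2676 (14.5%) changed at an adjusted p under 0.05. Of these, 1169 were higher and 1507 lower after irradiation. Most changes were small: the median size among changed genes was 0.37 on the log2 scale, and 20 genes rose and 61 fell by at least 2-fold. The irradiated and unirradiated values did not overlap for 2673 of the changed genes and for 34.7% of all genes, where chance alone gives 10% for 3 arrays against 3. The first principal component held 58.1% of the variance and separated the 3 irradiated from the 3 unirradiated arrays. Correlations between arrays ran from 0.996 to 0.998 within a group and from 0.992 to 0.994 between groups. Counts fell by more than 1.5 times when an unirradiated array was left out: 1584 genes changed without replicate 1 and 1471 without replicate 2.

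**Figure D1:**
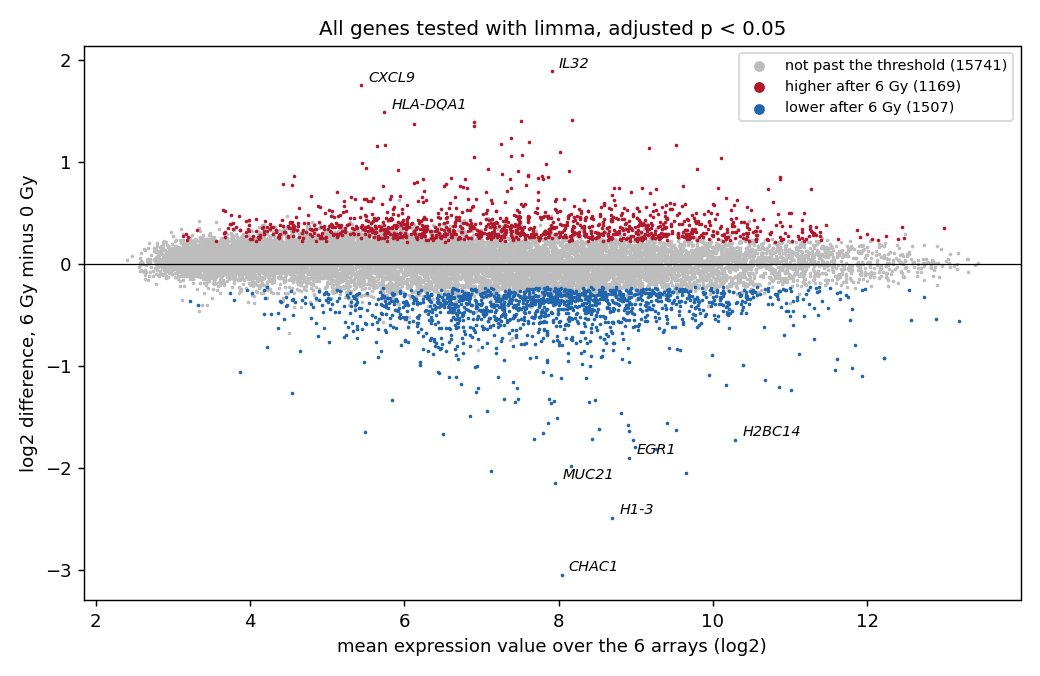
Log2 difference between irradiated and unirradiated means (vertical axis) against the mean log2 value over all 6 arrays (horizontal axis), 1 point per gene. Red points are the 1169 genes higher and blue points the 1507 genes lower after 6 Gy by limma, grey points did not pass, and the named points run from CHAC1 at -3.05 to IL32 at 1.89.

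Among the 12 largest increases were 3 chemokine genes and a chemokine receptor gene. CXCL10, whose product shares the receptor CXCR3 with that of CXCL9, rose by 1.41 on the log2 scale, and CCL22, which encodes a ligand of the receptor CCR4, rose by 1.39. CXCR5, encoding the receptor that guides B cells into follicles, rose by 1.35. A pair of HLA class II genes, which encode or regulate the proteins that present peptides to helper T cells, also stood among them: HLA-DQA1 rose by 1.48 and HLA-DOA by 1.23. KDELR3, encoding a receptor that returns escaped proteins to the endoplasmic reticulum, rose by 1.40, and the transcribed pseudogene ARB2BP by 1.37. The others were CHI3L1, which encodes a secreted chitinase-like glycoprotein (1.19), LBH (1.17), and the gene of the stem cell transcription factor SOX2 (1.16). The limma adjusted p of these genes lay between 6.29e-06 for ARB2BP and 3.01e-04 for HLA-DOA. The largest decreases beside CHAC1 were histone genes, ATF4-linked genes and 3 others: MUC21, encoding a cell-surface mucin (-2.15), the immediate early transcription factor gene EGR1 (-1.90) and PIP5KL1 (-1.72).

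**Figure D2:**
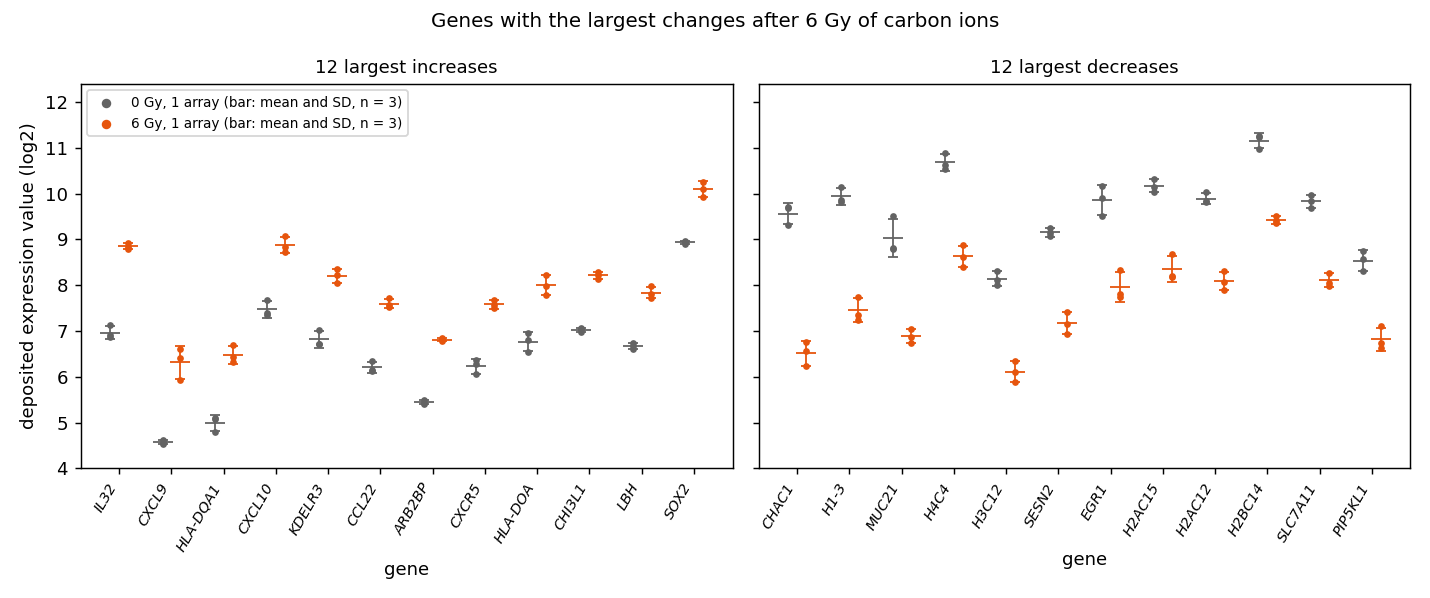
Deposited log2 expression values of the 12 genes with the largest increases and the 12 with the largest decreases, 1 point per array, with grey for 0 Gy and orange for 6 Gy; bars give the mean and SD of 3 arrays. By the rule that chose these genes, the 3 irradiated values of each lie apart from the 3 unirradiated values, as for IL32 with means of 6.97 and 8.85 and CHAC1 with 9.56 and 6.51.

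Replication-dependent histone genes, which supply the histones packed onto new DNA and whose mRNAs end in a stem-loop without a poly(A) tail, fell together. Of 57 measured, 42 fell, 0 rose and 15 did not pass, and 48 were lower when adjusted over the list alone. Their median log2 difference was -1.004, with a 95% bootstrap interval from -1.21 to -0.78, and camera placed them below other genes with an adjusted p of 6.52e-41. Its adjusted p with an estimated correlation was 0.104. Beside H1-3, the falls on the log2 scale included H4C4 (-2.05), H3C12 (-2.03), H2AC15 (-1.81), H2AC12 (-1.79), H2BC14 (-1.73), H2AC8 (-1.72), H4C2 (-1.63) and H4C9 (-1.56). These genes are close copies of one another, so probe sets may share signal and the value of a single member is uncertain. Small nucleolar RNAs, which also lack a poly(A) tail, moved the same way by less: 31 of 192 were lower and 1 higher (37 and 1 adjusted over the list alone), with a median of -0.09. The camera adjusted p was 7.47e-07, and 0.425 with an estimated correlation. The list's median level of 5.84 lay near the array medians, so many members were dim. The 114 small nucleolar and spliceosomal RNAs above the array median had a median difference of -0.22. SNORD96A differed by -1.22, SNORA38B by -1.18 and SNORA75 by -0.78.

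The integrated stress response raises the translation of ATF4, which then drives genes of amino acid synthesis, uptake and redox balance. Of 25 such genes measured, ATF4 itself among them, 21 fell, 0 rose and 4 did not pass. Adjusted over the list alone, 22 were lower and 1 higher. The mRNA of ATF4, named after its value was seen, fell by 1.14 on the log2 scale (limma adjusted p 3.80e-05). The median log2 difference was -0.71, with a camera adjusted p of 1.14e-22, or 0.076 with an estimated correlation. SESN2, a stress-induced inhibitor of growth signalling, fell by 1.98, and SLC7A11, the cystine importer, fell by 1.72. PHGDH, the first enzyme of serine synthesis, fell by 1.51 (from 8.73 ± 0.13 to 7.22 ± 0.04, mean ± SD, n = 3). DDIT3, encoding the pro-apoptotic factor CHOP, fell by 1.49 (from 7.59 ± 0.09 to 6.10 ± 0.09, mean ± SD, n = 3). Genes of the XBP1 and ATF6 branches, which enlarge the protein-folding capacity of the endoplasmic reticulum, went both ways: of 26 measured, 3 were higher and 4 lower, both in the full test and adjusted over the list alone. Their median was 0.05 and their mean -0.00035, and camera, which pointed lower, gave an adjusted p of 0.772. The sensor gene ERN1 fell by 0.54, while the chaperone gene HSPA5 rose by 0.27 and the translocon gene SEC61B by 0.24. With 1 array left out the limma call ended for SEC61B (each of the 6 in turn, adjusted p up to 0.0851) and HSPA5 (each except irradiated replicate 3, up to 0.0848).

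Heat shock genes, encoding chaperones and their partners, rose as a list. Of 17 measured, 9 rose, 0 fell and 8 did not pass (10 higher when adjusted over the list alone), with a median of 0.24. Camera gave an adjusted p of 1.69e-06, and 0.076 with an estimated correlation. HSPA4L rose by 1.06 (2.09-fold), the co-chaperone gene BAG3 by 0.85 (1.81-fold) and SERPINH1, encoding a collagen chaperone, by 0.58 (1.49-fold). NF-kappaB target genes, many of them inflammatory, included 9 higher and 3 lower of 26 (11 and 5 adjusted over the list alone). Their median was 0.15, with a camera adjusted p of 0.0431 and 0.459 with an estimated correlation. The members with the smallest p were CXCL10, CXCL8 (0.91) and ICAM1 (0.45), and without its chemokine genes the list did not pass, with an adjusted p of 0.303. Interferon-stimulated genes did not pass as a list: 3 of 35 rose and 0 fell, the same numbers adjusted over the list alone, with a median of 0.05 and a camera adjusted p of 0.427. The risers were SAMD9L (0.75), IFI6 (0.44) and OASL (0.41). Antigen presentation genes of class I passed in the lower direction, with 2 of 12 lower and 0 higher, the same numbers adjusted over the list alone, and a median of -0.09. The camera adjusted p was 0.0499, and 0.425 with an estimated correlation. NLRC5, the class I transactivator, fell by 0.43 and the immunoproteasome gene PSMB10 fell by 0.31, whereas ERAP2 differed by -0.18 (adjusted p 0.157 in limma). Calls that ended with 1 array left out were those by camera of NF-kappaB target genes (adjusted p 0.0587 without unirradiated replicate 1, 0.0565 without unirradiated replicate 3 and 0.0572 without irradiated replicate 3) and antigen presentation class I genes (each except unirradiated replicate 2, up to 0.0845, with a median of -0.14 without irradiated replicate 3). By limma they were OASL (0.0836 and 0.0859 without unirradiated replicates 1 and 2) and PSMB10 (each except irradiated replicate 2, up to 0.110).

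Classical p53 targets did not pass as a group. Of 28 measured, 5 were higher and 2 lower (7 and 4 adjusted over the list alone), with a median of 0.12 and a camera adjusted p of 0.486. The cyclin-dependent kinase inhibitor gene CDKN1A differed by 0.18 ± 0.10 (SE), which did not pass (limma adjusted p 0.246). MDM2, which encodes a ubiquitin ligase, was at the edge of the threshold with a log2 difference of 0.37 ± 0.11 (SE) and an adjusted p of 0.0499. For MDM2 the limma adjusted p ran from 0.0155 to 0.156 over the alternative settings. It missed the threshold without any 1 of 5 of the arrays, with array medians subtracted and with the sample number as a replicate block (0.0738). TIGAR rose by 0.53, while XPC, a damage sensor of nucleotide excision repair, and SESN2 were lower, and XPC fell by 0.54. Of 15 BCL2 family genes, 4 were lower and 0 higher (5 and 1 adjusted over the list alone). Their median was 0.02, their mean -0.12 and the camera adjusted p 0.174 in the lower direction. The 3 with the smallest p encode pro-apoptotic BH3-only proteins: PMAIP1 (-1.12), BMF (-0.70) and HRK (-0.40) all fell. The other that fell was the survival gene BCL2 (-0.30), named after its value was seen, and the survival gene MCL1 differed by -0.22 (adjusted p 0.0564 in limma). The death receptors and ligands counted 4 higher and 2 lower of 17 (4 and 3 adjusted over the list alone), with a median of 0.10 (0.01 to 0.13 with an array left out) and a camera adjusted p of 0.705. FAS rose by 0.35 and TNFRSF1B by 0.31, and CFLAR, an inhibitor of caspase-8 activation, fell by 0.37. The limma call ended with an unirradiated array left out for CFLAR (adjusted p 0.0611 and 0.0625 without replicates 1 and 2) and TNFRSF1B (0.0512 without replicate 1), and for BCL2 without unirradiated replicates 1 and 2 and irradiated replicate 1 (up to 0.1003).

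Among DNA repair genes, those of end joining and damage signalling fell as a list, with 10 lower and 0 higher of 24 (10 and 1 adjusted over the list alone) and a median of -0.18. The camera adjusted p was 5.34e-04, and 0.104 with an estimated correlation. RAD50, part of the complex that binds broken DNA ends, fell by 0.66, PARP1 fell by 0.39 and the damage kinase gene ATM fell by 0.37. Of 24 homologous recombination and Fanconi genes, 3 fell and 0 rose, the same numbers adjusted over the list alone: BRIP1 (-0.48), RAD51AP1 (-0.36) and FANCI (-0.29). The list's median was -0.04, with a camera adjusted p of 0.0455 and 0.425 with an estimated correlation. G1/S and DNA replication genes had 7 lower and 1 higher of 31 (8 and 2 adjusted over the list alone) and a median of -0.07, with a camera adjusted p of 0.0216 and 0.425 with an estimated correlation. PRIM1 (-0.46), the replicative helicase gene MCM7 (-0.43) and RFC4 (-0.39) fell, and the sliding clamp gene PCNA differed by -0.28 (limma adjusted p 0.0579). G2/M and mitosis genes went both ways, with 5 higher and 5 lower of 33 (7 and 8 adjusted over the list alone), a median of -0.06 and a camera adjusted p of 0.270. The kinetochore genes CENPE (-1.11) and CENPF (-0.68) and the proliferation marker MKI67 (-0.95) fell, while cyclin B1 (CCNB1) differed by 0.08 (limma adjusted p 0.527). Camera's call ended for homologous recombination and Fanconi genes without unirradiated replicate 1 and irradiated replicate 3 (adjusted p 0.0751 and 0.0723) and for G1/S and DNA replication genes without irradiated replicate 3 (0.0757), whose median was -0.10 without unirradiated replicate 3. Limma's call ended for RAD51AP1 without unirradiated replicates 1 and 2 and irradiated replicates 1 and 3 (up to 0.139), for FANCI without unirradiated replicates 2 and 3 and irradiated replicate 1 (up to 0.0925) and for BRIP1 without unirradiated replicates 2 and 3 (0.0529 and 0.0501), and PCNA was called without irradiated replicate 3 (0.017).

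Immediate early genes, transcribed within minutes of a stimulus, had 8 lower and 1 higher of 26 (9 and 3 adjusted over the list alone) and a median of -0.04. The camera adjusted p was 0.00973, and 0.425 with an estimated correlation. NR4A2 (-0.96), ATF3 (-0.71) and MYC (-0.33) fell. Cytosolic ribosomal protein genes passed in the lower direction with a small median of -0.04, 2 of 57 lower and 0 higher, the same numbers adjusted over the list alone. The camera adjusted p was 0.0265, and 0.648 with an estimated correlation. RPS24 (-0.39) and RPS21 (-0.31) fell, and RPS13 differed by -0.21 (limma adjusted p 0.073). Ribosome biogenesis genes counted 2 higher and 2 lower of 27, the same numbers adjusted over the list alone, with a median of -0.03 and a camera adjusted p of 0.316. DKC1 fell by 0.33, UTP20 fell by 0.28 and PES1 rose by 0.27. Of 28 proteasome subunits, PSMA2 alone passed (0.25), and 0 passed when adjusted over the list alone; the median was 0.05 and the camera adjusted p 0.270, with PSMB5 at 0.22 and PSMD1 at 0.16. Camera's call ended for immediate early genes without irradiated replicate 3 (adjusted p 0.0518) and for cytosolic ribosomal proteins without unirradiated replicate 3 and irradiated replicate 3 (0.126 and 0.422). Without unirradiated replicate 2 and irradiated replicate 2 the medians of immediate early genes were -0.0691 and -0.074 and those of cytosolic ribosomal proteins -0.0627 and -0.0736, and the last was -0.0145 without irradiated replicate 3. Limma's call ended with 1 array left out for RPS24 (unirradiated replicates 2 and 3, irradiated replicates 1 and 3, adjusted p up to 0.0731), RPS21 (unirradiated replicates 1 and 2, irradiated replicate 1, up to 0.0577), PES1 (any unirradiated array, irradiated replicate 2, up to 0.104), UTP20 and PSMA2 (each except irradiated replicate 2, up to 0.086 and 0.125).

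Genes of plasma cell identity leaned lower but did not pass camera as a list. Of 21 measured, 6 fell and 2 rose (7 and 3 adjusted over the list alone), with a median of -0.07. The adjusted p was 0.0714 by camera and 0.0368 by fry. DERL3, which serves degradation from the endoplasmic reticulum, fell by 0.58 and the integrin gene ITGB7 fell by 0.55, while SLAMF7, which encodes a surface receptor of plasma cells, rose by 0.55. The transcription factor gene IRF4 differed by -0.02 ± 0.07 (SE). B cell genes had 5 higher and 2 lower of 18 (5 and 3 adjusted over the list alone) and a median of 0.13. Their adjusted p was 0.0714 by camera and 0.00719 by fry. HLA class II members led them, with HLA-DPB1 up by 0.83 and HLA-DPA1 by 0.74 beside HLA-DQA1. Adhesion and migration genes had 8 higher and 3 lower of 29 (8 and 4 adjusted over the list alone), a median of 0.04 and a camera adjusted p of 0.507, and CXCR3 rose by 0.48.

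Markers of cell types other than B cells and plasma cells were mostly dim. Monocyte and macrophage markers passed in the higher direction with a median of 0.15, although 1 of 17 was higher and 0 lower, also adjusted over the list alone. The camera adjusted p was 0.0455, and 0.514 with an estimated correlation. ITGAM rose by 0.52, and CD163 and S100A8, with unirradiated means of 3.40 and 3.51, differed by 0.26 and 0.21 (limma adjusted p 0.0839 and 0.111). T and NK cell markers had 2 higher and 1 lower of 18, the same numbers adjusted over the list alone, with a median of 0.13 and a camera adjusted p of 0.128. CD5 rose by 0.38 and LCK by 0.26, and CD4 fell by 0.38. Fibroblast and epithelial markers had 4 higher and 1 lower of 16 (5 and 2 adjusted over the list alone), with a median of 0.14 and a camera adjusted p of 0.0714. KRT5 rose by 0.57 and COL3A1 by 0.29, and EPCAM fell by 0.39. Of 13 erythroid and megakaryocyte markers 0 passed limma, also adjusted over the list alone, with a median of 0.04 and a camera adjusted p of 0.657; GATA1 differed by 0.21, TAL1 by 0.25 and KLF1 by 0.13. Camera's call of monocyte and macrophage markers ended without unirradiated replicate 3 (adjusted p 0.126, median 0.08) and without each irradiated array (up to 0.0712), and fibroblast and epithelial markers were called without irradiated replicate 1 (0.0464, median 0.23). Limma's call ended with 1 array left out for LCK (each except irradiated replicate 2, adjusted p up to 0.147), CD4 (each except irradiated replicate 3, up to 0.0957), COL3A1 (each except irradiated replicate 1, up to 0.0845), CD5 (0.0861 and 0.0602 without replicate 2 of either dose) and EPCAM (0.0541 and 0.0511 without unirradiated replicates 2 and 3).

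The metabolic and organelle lists did not pass. Hypoxia and glycolysis genes had 2 higher and 1 lower of 24, the same numbers adjusted over the list alone, with a median of -0.01 and a camera adjusted p of 0.629. VEGFA fell by 0.96, P4HA2 rose by 0.71 and the glucose transporter gene SLC2A1 by 0.36. NRF2 targets had 4 higher and 3 lower of 22, the same numbers adjusted over the list alone. Their median was 0.01, their mean -0.02 and the camera adjusted p 0.897 in the higher direction. NQO1 rose by 0.61, and NFE2L2, which encodes NRF2 itself, fell by 0.59. Cholesterol synthesis genes had 1 higher and 3 lower of 18 (1 and 5 adjusted over the list alone), with a median of 0.02, a mean of -0.05 and a camera adjusted p of 0.274 in the lower direction. INSIG1 fell by 0.47, SREBF2 fell by 0.38 and NSDHL rose by 0.37. Lysosome and autophagy genes had 4 higher and 9 lower of 29, the same numbers adjusted over the list alone, with a median of -0.03 and a camera adjusted p of 0.120. HEXA fell by 0.73, CTSB fell by 0.51 and ATP6V0D1 rose by 0.49. The reference genes ACTB and GAPDH differed by 0.03 ± 0.06 and 0.05 ± 0.07 (SE).

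**Figure D3:**
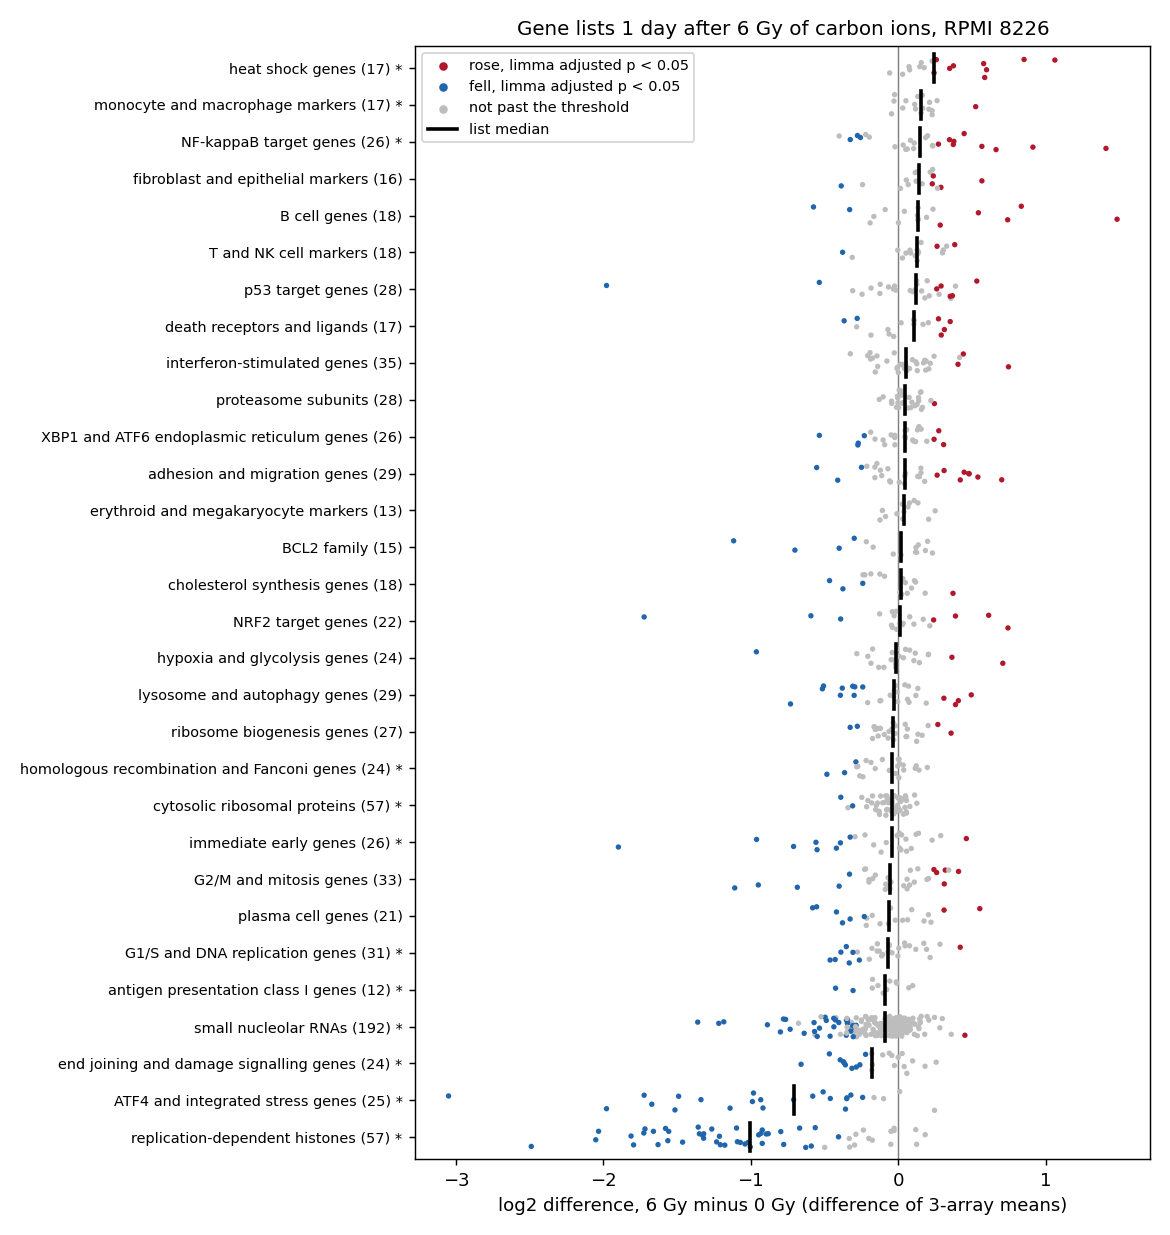
Log2 difference between irradiated and unirradiated means for each measured member of the 30 gene lists tested, with the number of members in brackets; black bars are list medians and an asterisk marks the 12 lists that passed camera with its preset correlation. Red and blue members rose or fell by limma and grey members did not pass; the histone list has a mean of -0.95, the ATF4 list a median of -0.71 and the heat shock list a median of 0.24.

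Of 30 lists, camera with its preset correlation called 12, 3 higher and 9 lower. With an estimated correlation it called 0 (4 at an unadjusted p under 0.05). Fry called 9, among them B cell and plasma cell genes (adjusted p 0.00719 and 0.0368), which camera did not call. Fry did not call small nucleolar RNAs, homologous recombination and Fanconi genes or monocyte and macrophage markers (adjusted p 0.089 each). Nor did it call antigen presentation class I genes (0.0566) or cytosolic ribosomal proteins (0.305). Regrouping the same 6 arrays into other sets of 3 against 3, which mix the doses, gave up to 8 calls. The histone, ATF4, small nucleolar RNA, heat shock and end joining lists were the 5 still called without irradiated replicate 3, and quantile normalization or leaving out the dimmest genes left 6.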

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

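The tests of RNA without a poly(A) tail, of S phase, of endoplasmic reticulum load and of culture density were chosen after the results they bear on were seen; the tests of a single deviating array and of other splits were not.

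Probe sets outside the gene comparison also carried a difference between the doses. In a limma fit of all probe sets, 362 of the 12083 that the annotation does not list passed an adjusted p of 0.05, 111 higher and 251 lower. Of the 1754 listed with several genes, 256 passed, 60 higher and 196 lower. No gene is named from either kind.

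With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2676 changed genes and the highest other split 0; for genes higher these were 1169 and 0, and for genes lower 1507 and 0. In each case 1 of the 10 splits, the real one, gave a count as large. For lists called by camera with its preset correlation the real split gave 12 and the highest other 8, again with 1 of 10 as large. Every other split puts arrays of both doses into each of its groups. A dose difference then widens the spread within groups, so a gene count of 0 was likely from the start. The list calls of such splits may hold part of the dose difference, so they do not show how many calls are false. A call of this kind on a list with a small median still carries little weight by itself, as camera with an estimated correlation called 0 lists.

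Of 57 histone genes 42 fell, and the list's median was -1.004. Poorer recovery or labelling of RNA without a poly(A) tail should lower small nucleolar and spliceosomal RNAs too, and the 114 of these above the array median had a median difference of -0.2188 (95% bootstrap interval down to -0.247). That lies well above -0.50, which is the histone median divided by 2. It argues against this as the whole cause only if both kinds of RNA would lose signal alike, which was not tested. Poorer recovery or labelling may account for part of the fall. Fewer cells in S phase could lower histone mRNA, which accumulates in that phase; the G1/S and DNA replication genes had a median of -0.06753 (95% bootstrap interval from -0.178 to -0.0024), also above -0.50, but they are not confined to that phase as histone mRNA is and need not fall as far, and camera's call is lost with an estimated correlation (adjusted p 0.425), so the values leave it open. An effect of the dose on histone transcription or mRNA stability stays open and untested.

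Of 25 ATF4-linked genes 21 fell, and the list's median was -0.71. A single deviating array is argued against, since with each array left out in turn the list's median stayed between -0.766 and -0.6272. A lower load on the endoplasmic reticulum, which also feeds ATF4, would be expected to lower XBP1 and ATF6 targets; their median was 0.04631, with a 95% bootstrap interval from -0.0702, above -0.36, the ATF4 median divided by 2. Denser or more depleted unirradiated cultures could raise amino acid stress at 0 Gy and cannot be told apart from the dose, as density is not recorded and would go with it; the hypoxia and glycolysis genes had a median of -0.01308, which decides nothing. An effect of irradiation itself on the pathway stays a hypothesis.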

How the results depend on the processing

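The alternatives that counted identical histone probe sets once and that took HLA class II genes from the B cell list or chemokines from the NF-kappaB list were chosen after seeing the data; the others were planned. Counting identical sets once gave a histone median of -1.01, and the B cell list without HLA class II genes stayed uncalled (camera adjusted p 0.705). The alternative of log2(value + 16) was not run because the table already is on a log scale.

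The counts are of genes changed after 6 Gy of carbon ions, of genes higher after 6 Gy and of genes lower after 6 Gy. Over the limma alternatives at an adjusted p under 0.05 with no fold minimum, 1471 to 3237 changed. Counts moved over 1.5 times with fewer arrays: leaving out each array in turn gave 1471 to 2184 changed genes, 619 to 887 higher and 852 to 1324 lower. The lowest came without unirradiated replicate 2; higher genes were 668 without unirradiated replicate 1 and 649 without 3, and lower genes 916 without unirradiated replicate 1 and 999 without irradiated replicate 1. Called in the same direction whichever array was left out were 1202 genes, and 0 turned. All probe sets gave 729 higher. An adjusted p under 0.01 gave 1077 changed, 384 higher and 693 lower, a fold of at least 1.5 gave 388, 111 and 277, and one of at least 2 gave 81, 20 and 61, by construction. A plain equal-variance test without a shared prior gave 956, 420 and 536 (4641 genes at an unadjusted p under 0.05).

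The replicate block, with the sample number in the model, gave 1919 genes changed after 6 Gy of carbon ions, 765 genes higher after 6 Gy, 1154 genes lower after 6 Gy and 11 lists. The list not called was antigen presentation class I genes (camera adjusted p 0.0559), and 10 named genes were not called by limma: MDM2 (adjusted p 0.0738), SEC61B (0.071), LCK (0.0649), CD5, CD4, COL3A1, UTP20, PES1, PSMA2 and PSMB10. No other such call changed. Residuals of arrays with the same number correlated at -0.04, 0.10 and -0.11, giving no sign of pairing.

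The gene lists called were 12 in the report and 5 to 12 with an array left out, lowest without irradiated replicate 3, with 9 without unirradiated replicate 1 and 8 without unirradiated replicate 3. They were 6 with quantile normalization, 6 without the dimmest genes and 0 with an estimated correlation. Array weights ended 3 calls. An intensity trend with a robust prior ended 1 and added 2, and fry ended 5 and added 2. The cause was not tested. The test turned direction for these uncalled results: NRF2 target genes in the test, with medians from -0.0115 to 0.0333 with an array left out (-0.0115 without irradiated replicate 2, 0.00287 without unirradiated replicate 1) and 0.0126 by fry; XBP1 and ATF6 endoplasmic reticulum genes in the test, with medians of 0.0458 without the dimmest genes and 0.0433 with quantile normalization; IRF4, from -0.0651 to 0.0427 with an array left out, the last without irradiated replicate 2; erythroid and megakaryocyte markers to -0.0117 and hypoxia and glycolysis genes to 0.0323 with quantile normalization. Other medians near 0 crossed 0 without the test turning, as for lysosome and autophagy genes (0.00321 without unirradiated replicate 2) and hypoxia and glycolysis genes (0.00678 and 0.0129 without unirradiated replicates 1 and 2). With no detection calls, signal over background limits what dim genes can show.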

Other observations

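The 3 gene families below, the genes named from them and the tests of monocytes and of an interferon response were chosen after seeing the data.

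Of 10 HLA class II genes measured, 8 rose and 0 fell, with a median log2 difference of 0.79. Beside HLA-DQA1 and HLA-DOA, HLA-DOB rose by 1.05 (2.07-fold), HLA-DMB by 0.93, HLA-DMA by 0.74 and HLA-DRB5 by 0.53; the products of HLA-DMA and HLA-DMB load peptides onto class II molecules. HLA-DQB1 (0.18) and the pseudogene HLA-DPB2 (0.33) did not pass. Of 37 chemokine genes, 8 rose and 0 fell, with a median of 0.11; CCL3 and CCL5 each rose by 0.57, CXCL16 by 0.29 and CXCL3 by 0.29, the last called by limma only with all 6 arrays or without irradiated replicate 3 (adjusted p otherwise up to 0.117). Members already named in the report drew attention to these families, so named genes were left out of a test against other genes (Fisher's exact test, two-sided, adjusted over the 3 families). Of the 6 HLA class II genes left, 4 rose, against 6.14% of other genes (adjusted p = 5.82e-04). Of the 33 chemokine genes left, 4 rose, against 6.15% of other genes, which did not pass (adjusted p = 0.143). The families were still chosen with all values in view, so these p-values describe the counts and give no independent support. Members of a family are not independent, and HLA genes are close copies, so the value of a single member is uncertain.

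Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids and several of which are ATF4 targets, leaned lower. Of 19 measured, 7 fell and 2 rose, with a median of -0.24; no test of the family is given, as it was chosen for these falls. CARS1 (-0.81), GARS1 (-0.70), MARS1 (-0.62) and SARS1 (-0.55) fell, while RARS1 rose by 0.33 and FARSA by 0.28. The limma call ended for RARS1 without unirradiated replicate 1 (adjusted p 0.0518) and for FARSA without any 1 of the unirradiated arrays (up to 0.0667).

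Monocytes or macrophages in the irradiated cultures would bring their abundant transcripts along with HLA class II mRNA, and the values argue against them as the source of that rise. All 17 monocyte and macrophage markers had a median of 0.1548 (95% bootstrap interval up to 0.212), below the interval of HLA class II genes, which starts at 0.532; ITGAM alone rose (0.52), and camera called the list higher (adjusted p 0.0455, or 0.514 with an estimated correlation). After irradiation LYZ stood at 3.32, CD14 at 4.91 and TYROBP at 6.37, and none of them passed. CD68 was bright at both doses, at 9.97 on the unirradiated and 9.94 on the irradiated arrays, and did not pass. For chemokines a monocyte or macrophage source stays open, as their median of 0.112 has an interval from 0.0684, which overlaps that of the markers. A broad interferon response should raise the interferon-stimulated genes listed here, whose median was 0.05279 (95% bootstrap interval up to 0.129), below the bound of 0.25 set for it. That argues against a broad rise of the listed genes. Their median level of 5.77 lies near the array medians, so dim members could miss a rise. A response limited to few genes or to genes outside the list cannot be judged from this median. An effect of irradiation on HLA class II and chemokine genes within the myeloma cells stays a hypothesis, and culture differences that go with the dose were not tested for it.

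Longer genes tended to slightly lower values on the irradiated arrays. Across 10622 protein-coding genes above the array median, histones left out, Spearman's rho between gene length and log2 difference was -0.18, where genes are not independent replicates. Between single arrays of different dose rho ran from -0.21 to -0.11, and between arrays of the same dose from -0.13 to 0.14. The sign within a dose depends only on the order of subtraction. The largest same-dose values, 0.14 and -0.13, both involved unirradiated replicate 2, and the others ran from -0.02 to 0.07. Pairs of the same dose with that array thus differed as much as some of different dose, so the trend is not set apart from variation between arrays.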
